A study of Danio rerio with 4 samples.

How the data were processed

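The series measured gene expression in pooled zebrafish heads by QuantSeq 3' mRNA sequencing, in which each read marks the 3' end of a polyadenylated transcript. Per the labels, 2 libraries came from wildtype controls and 2 from animals given Cas9 and a guide RNA against cspg4, here called crispants. The design text of the series states 20 animals per group and 3 independent replicates, and 2 libraries per group were analysed here. The labels do not say what was separate between replicates of a group, so the p-values measure the spread between these libraries, which can be technical. The age of the animals, the guide sequence and the editing rate are not given in the sources used here.

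The main file held raw counts per Ensembl gene as deposited by the authors, with 31901 genes and whole-number values in 4 columns, 1 per library. The submitters' processing notes name STAR 2.6.1d, HTSeq 0.9.1, Subread and limma and the builds GRCz11 and danRer11, without saying which step each tool served. The strand setting and the treatment of reads that map to several genes are not given in the sources used here. Values of genes with near-identical copies, such as the gamma crystallins, the keratins and some ribosomal protein genes, are therefore uncertain for the single copy. Genome coordinates are not printed, since no annotation of that build was used here.

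A second table, the authors' deposited table of changed genes, was read beside the counts. Per the file headers it gives a group score for crispants and for controls, and these deposited scores lay on a log-like scale with values below 0, of unstated base. Its title also carries what reads as the name of a protein variant. The sources used here do not say which animals or libraries gave each score. Its deposited fold change is a ratio of the control score to the crispant score, and its deposited log2 value is the log2 of that ratio. The deposited p-value columns held raw and adjusted values, with the adjustment method not stated. Metabolite and network tables of the series concern individual people and were not used here.

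Library sizes were scaled by TMM in edgeR 4.0.16 under R 4.3.3, and genes with low counts were removed by the default filter of edgeR with the groups given, which left 12481 genes and took out 19420. The groups were compared with edgeR's quasi-likelihood test, 2-sided, with no covariates, 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Printed log2 fold changes are crispant over control, and each standard error is the fold change divided by the square root of the F statistic. Printed CPM values are relative to the TMM-scaled library size, computed here from the deposited counts, with the mean and SD over 2 libraries per group. The standard errors rest on the dispersion shared across genes as well as on these libraries. A gene with 0 counts in both libraries of a group was given a lower bound of its fold, computed against 3 counts over that group. Floors cover counting error only, and 3' reads without molecular identifiers are not independent molecules. Bootstrap intervals cover the draw of list members and exact intervals the draw of genes. Neither kind of interval holds the spread between libraries.

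Total counts ran from 5874857 to 6243650 per library, so that 3 counts corresponded to 0.480 to 0.511 CPM. The common biological coefficient of variation was 36.2%. On simulated counts for the same 12481 genes and the same comparison, with 200 genes changed in each of 5 simulations, the test called 10.7% of genes changed 2-fold, 63.6% of those changed 4-fold and 93.0% of those changed 8-fold. Other members of the lysosome and autophagy list were raised by 0.5 log2 units in each simulation and did not count as false. False calls made up 4.74% of the calls. The simulated genes varied independently, with the same dispersion in both groups, and the 200 changed genes had at least 5 CPM. In the real counts the controls differed more than the crispants (r = 0.886 and 0.940 across genes), so these rates need not hold for them.

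The choice of 48 gene lists, the tests, the alternatives and the rule for named genes were set before the data were examined. Of 2148 list entries, 2039 matched a gene by symbol, 17 through the table of gene names and 22 through synonyms in the RefSeq gene table, 22 were other names of a gene already in the list, and 48 were not matched. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 48 lists. The same test with an estimated correlation, and fry, stood beside it. Camera compares a list with the other genes, and fry tests whether the members of a list move, on balance, 1 way.

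The rule for named genes took cspg4, then the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM, both crispants on the same side of both controls, and no clone-based name. It then took up to 2 rising and 2 falling genes per list with the smallest adjusted p, or the 2 with the highest mean CPM where no member passed. Genes named outside this rule are said to have been chosen after their values were seen.

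Alternatives were DESeq2 size factors in edgeR, library size alone, no filter on low counts, a filter of 1 CPM in 2 libraries, the replicate number as a block, robust dispersions, DESeq2 1.42.0, limma-voom, an FDR of 0.1, a threshold of 1 on the absolute log2 fold change, a prior count of 0.5 for the list tests, and each library left out in turn. A fit without mitochondrial genes and the very abundant CR383676.2, which removed 38 genes before scaling, was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.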

Results

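Transcript counts were obtained from pooled heads of zebrafish whose cspg4 gene was targeted with Cas9 and a guide RNA, and from wildtype controls, with 2 libraries per group. Cspg4 is a transmembrane chondroitin sulfate proteoglycan, known in mammals as a marker of oligodendrocyte precursors and pericytes. Crispants are animals injected with the editing reagents and studied in the same generation, so that their cells carry a mixture of edits. The comparison asks how gene expression in the head differs when cspg4 is targeted, in a series concerned with CSPG4 and neurodevelopment.

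Total counts were 5891096 and 5874857 in controls 1 and 2, and 6025559 and 6243650 in crispants 1 and 2. Counts above 0 were found for 14801 and 13828 genes in the controls and for 16230 and 17253 genes in the crispants, of 31901 in the table. Mitochondrial genes took 23.4% and 22.2% of control counts and 26.6% and 33.2% of crispant counts. Across genes, log2 CPM correlated with r = 0.940 between the crispants and r = 0.886 between the controls, and genes are not independent replicates. The first principal component held 61.5% of the variance and placed the crispants at 62.3 and 61.5 and the controls at -34.8 and -89.0, so that the controls lay further apart than the crispants.

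The targeted gene, cspg4 (ENSDARG00000078227), had 0 counts in all 4 libraries. This count of 0 allows up to 0.509 and 0.511 CPM in the controls and 0.498 and 0.480 CPM in the crispants. The level of cspg4 could therefore not be compared, and 3' tags need not fall after an edit upstream of them.

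In the crispant heads 14 of 46 epidermal, 21 of 38 lens, 35 of 69 ribosomal protein and 8 of 36 liver genes fell, and 7 of 27 neuronal genes rose. These lists passed camera with a preset correlation of 0.01, and with an estimated correlation each had adjusted p = 0.871. That value is a tie of the Benjamini-Hochberg adjustment, shared by the 13 lists past camera with the preset correlation. Before adjustment, camera with an estimated correlation gave p = 0.242, 0.120, 0.176, 0.399 and 0.391 in the order above. The estimated correlations were 0.320, 0.311, 0.345, 0.484 and 0.709. The periderm keratin gene cyt1 fell 7.22-fold, from 2234 ± 444 to 309 ± 22.6 CPM (SD, n = 2), and the ribosomal protein gene rpl36 fell 5.17-fold, from 6851 ± 1691 to 1326 ± 10.4 CPM. The lens gene cryba2b fell 4.54-fold, from 1998 ± 163 to 440 ± 39.0 CPM. The synaptic vesicle gene vamp2 rose 7.72-fold, from 40.3 ± 2.39 to 311 CPM (270 and 353 in the libraries), and mmp13a, a collagenase, rose 13.4-fold, from 9.41 ± 5.67 to 126 ± 5.26 CPM. By edgeR's quasi-likelihood test 672 of 12481 genes passed, 354 higher and 318 lower, and 3064 genes had an unadjusted p below 0.05. Changes of at least 2-fold made up 341 of the rises and 294 of the falls. Without control 1 or control 2 the count was 4128 or 2188, and without crispant 1 or crispant 2 it was 192 or 198. Of the 354 rises, 112 and 97 remained without crispant 1 and crispant 2, and of the 318 falls, 72 and 87 remained. Scaling by library size alone gave 66.4% rises among the calls against 52.7% with TMM, and moved the median log2 fold change of all genes from 0.02 to 0.12.

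**Figure D1:**
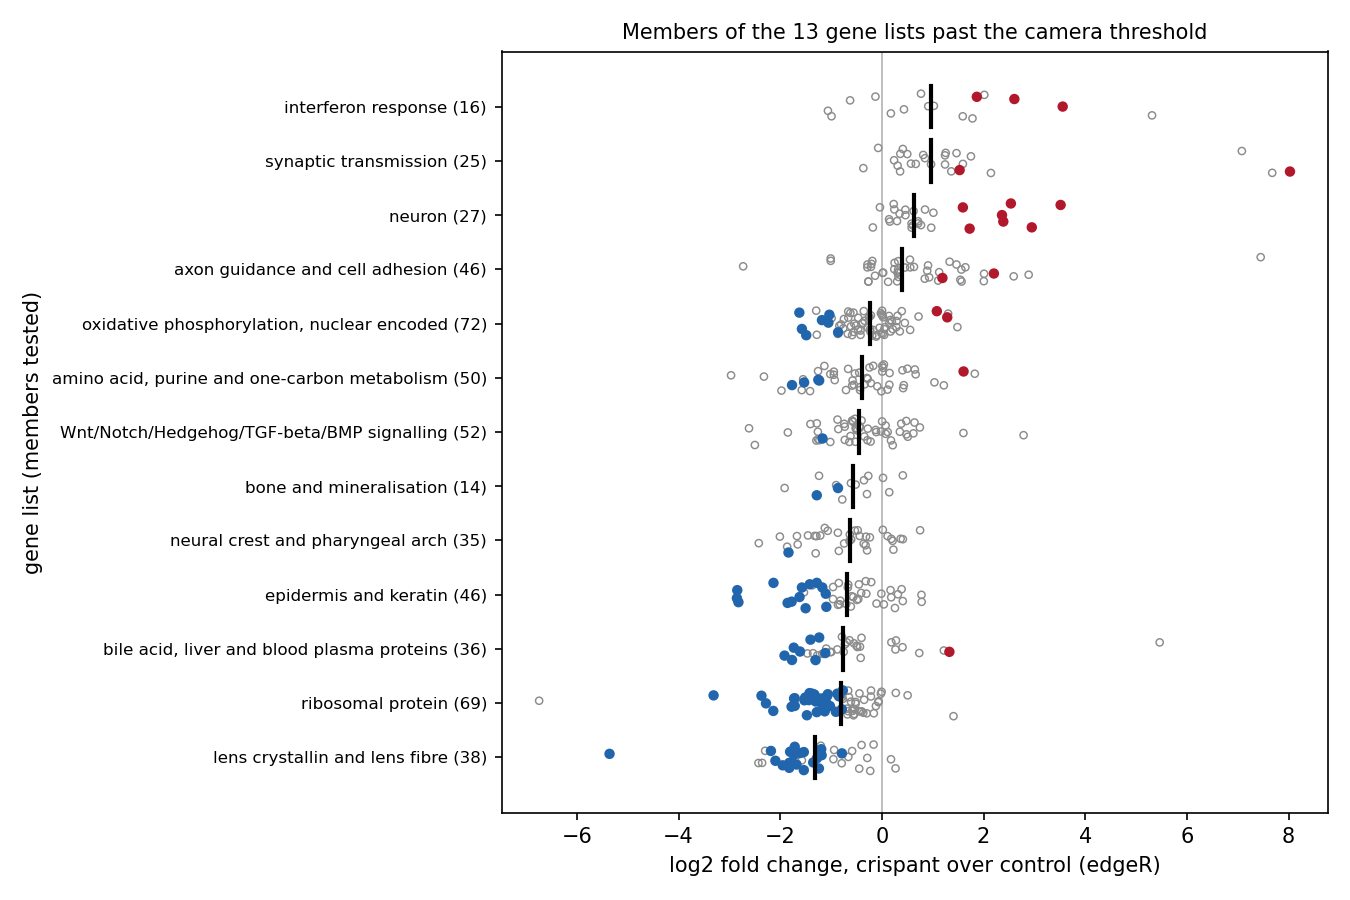
Log2 fold changes, crispant over control, of the tested members of the 13 gene lists past camera's threshold with the preset correlation. Each point is a gene, filled red or blue where it rose or fell past edgeR's threshold and open where it did not, and black bars mark list medians, which run from -1.31 for lens genes to 0.97 for synaptic and interferon genes.

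The largest rises started from controls near the floor. Dnm1a, the dynamin of synaptic vesicle endocytosis, went from 3 and 0 counts in the controls to 198 and 242 in the crispants (log2 fold change 6.94 ± 0.72 SE, edgeR adjusted p = 0.00672). Gnsb, a glucosamine sulfatase gene, had 0 counts in both controls and 118 and 56 in the crispants, at least 51.2-fold higher. The others were nrxn2a (a neurexin, 5.84 ± 1.00), jph1a (a junctophilin, 5.23 ± 0.88), tmod2 (a neuronal tropomodulin, 4.73 ± 0.81), thsd7aa (4.64 ± 1.01), myo10l3 (a myosin X, 4.58 ± 0.84) and ifi35 (4.22 ± 0.65), with standard errors after each log2 fold change. The largest falls were crygm2b (-5.36 ± 0.84) and crygm5 (-4.88 ± 0.74), both gamma crystallins, then jac8 (-4.33 ± 0.79), the collagen gene col18a1b (-3.57 ± 0.68), the lectin gene CLEC3A (-3.46 ± 0.42), the mitochondrial nuclease gene mgme1 (-3.45 ± 0.72), the gamma-glutamyl hydrolase gene ggh (-3.34 ± 0.75) and rps12 (-3.31 ± 0.62). Dnm1a, crygm2b, crygm5 and CLEC3A passed edgeR's threshold with each library left out. The other 12 lost the call without crispant 1, crispant 2 or both.

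Of 46 tested genes of the epidermis and keratin list, 14 fell, 0 rose and 32 did not pass, and 22 fell and 1 rose when adjusted over the list alone. Cyt1 (-2.85 ± 0.22, edgeR adjusted p = 0.00474) and its close relative cyt1l (-2.84 ± 0.24, 944 ± 232 to 131 ± 0.307 CPM) led the list, and both passed with each library left out. Claudin e, cldne, stood at 139 and 142 CPM in the groups (0.04 ± 0.26), and the periderm keratin krt4 did not pass (-0.83 ± 0.21, edgeR adjusted p = 0.0563). Both of these were chosen after their values were seen. Camera placed the list below the other genes with the preset correlation (adjusted p = 1.43e-06) and did not with an estimated correlation (adjusted p = 0.871). The list's median in control 2 was 0.38 log2 units above control 1, against -0.03 between the crispants, and its crispant median lay -0.45 and -0.90 from controls 1 and 2. Counts of falling members were 30 and 19 without control 1 and control 2, and 6 and 8 without crispant 1 and crispant 2.

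Lens genes had the lowest median of the 48 lists (-1.31). Of 38 tested members 21 fell, 0 rose and 17 did not pass, and 30 fell when adjusted over the list alone. Cryba2b (-2.18 ± 0.19, edgeR adjusted p = 0.00474) and cryba1l1 (-1.82 ± 0.17, 6253 ± 537 to 1767 ± 62.6 CPM), both beta crystallins of the lens fibre, passed with each library left out. The list passed camera with the preset correlation (adjusted p = 1.21e-13), with adjusted p = 0.871 with an estimated correlation. Here the controls differed by a list median of -0.19 and the crispants by -0.12, and the crispants lay -1.44 and -1.33 from controls 1 and 2. Without control 1, control 2, crispant 1 and crispant 2 the members that fell numbered 27, 31, 14 and 13. Gamma crystallin genes are near-identical copies, so that values of single copies are uncertain.

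Ribosomal protein genes fell in 35 of 69 tested members, 0 rose and 34 did not pass. Adjusted over the list alone, 50 fell and 2 rose. Rpl36 (-2.37 ± 0.21, edgeR adjusted p = 0.00499) and rpl17 (-1.78 ± 0.17, 3988 ± 44.5 to 1164 ± 8.38 CPM), parts of the large subunit, passed with each library left out. The list median was -0.80 (camera adjusted p = 1.21e-13 with the preset correlation, adjusted p = 0.871 with an estimated correlation). Without control 1, control 2, crispant 1 and crispant 2, 56, 52, 18 and 20 members fell.

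Among nuclear genes of oxidative phosphorylation, 7 of 72 fell, 2 rose and 63 did not pass, with 12 falls and 3 rises when adjusted over the list alone. Atp5po, a subunit of ATP synthase, fell (-1.62 ± 0.21), as did ndufa3 of complex I (-1.57 ± 0.22). Cox6a1 of complex IV (1.08 ± 0.19) and uqcrb of complex III (1.28 ± 0.29) rose. The list lay below the other genes by camera (adjusted p = 0.0130, and adjusted p = 0.871 with an estimated correlation), and 0 of its members rose or fell without crispant 1 or crispant 2. Of 13 mitochondrially encoded genes 1 rose, mt-atp6 (0.90 ± 0.19), and 12 did not pass, with the same counts when adjusted over the list alone. That rise lost the threshold without crispant 2 (edgeR adjusted p = 0.143). The share of counts taken by the most abundant mitochondrial gene was 13.5% and 13.0% in the controls and 15.8% and 22.2% in the crispants.

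Liver and plasma protein genes fell in 8 of 36 tested members, 1 rose and 27 did not pass, with 19 falls and 2 rises when adjusted over the list alone. Fabp10a, the liver fatty acid binding protein, fell 3.77-fold from 776 ± 222 to 206 ± 2.13 CPM, and rbp4, the plasma retinol carrier, fell 3.06-fold from 1738 ± 550 to 569 ± 17.9 CPM. Both passed with each library left out. The copper oxidase gene cp rose (1.33 ± 0.28) and lost the threshold without crispant 1 (edgeR adjusted p = 0.250) or crispant 2 (0.244). Camera gave adjusted p = 7.54e-04 for the list with the preset correlation and adjusted p = 0.871 with an estimated correlation. Control 2 exceeded control 1 by a list median of 0.63, and falling members numbered 25 and 13 without control 1 and control 2, and 2 and 3 without crispant 1 and crispant 2.

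**Figure D2:**
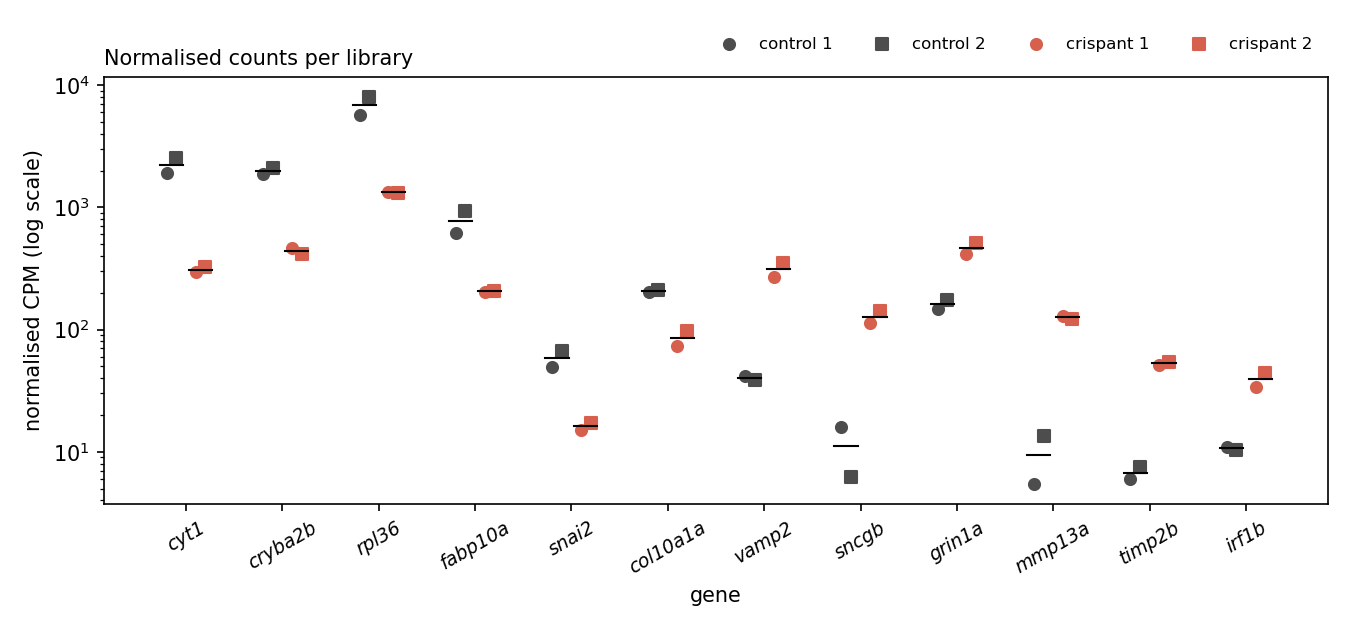
Normalised CPM, on a log axis, of 12 named genes in each library, with controls in grey, crispants in red and black bars at group means of 2 libraries. The crispants lie on 1 side of both controls for each gene shown, with cyt1 at 293 and 325 CPM in crispants against 1920 and 2548 CPM in controls.

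Neuronal genes rose in 7 of 27 tested members, 0 fell and 20 did not pass, with 10 rises when adjusted over the list alone. Vamp2 (2.95 ± 0.24, edgeR adjusted p = 0.00474) and the synuclein gene sncgb (3.52 ± 0.42, 11.1 ± 6.79 to 127 ± 20.1 CPM) passed with each library left out. Of 25 genes of synaptic transmission 2 rose, 0 fell and 23 did not pass, and 10 rose when adjusted over the list alone. These were grin1a, the obligate NMDA receptor subunit (1.53 ± 0.22, 161 ± 18.4 to 463 ± 71.7 CPM), and gria3a, an AMPA receptor subunit with 0 counts in both controls and 28 and 40 in the crispants, at least 20.4-fold higher. Grin1a lost the threshold without crispant 2 (edgeR adjusted p = 0.0677), and gria3a without crispant 1 (0.192) or crispant 2 (0.433). In the list of axon guidance and cell adhesion 2 of 46 rose, plxna3 (a semaphorin receptor, 47 and 20 counts in controls and 168 and 176 in crispants) and ephb2b (an ephrin receptor, 1.19 ± 0.27), 0 fell and 44 did not pass, with 3 rises when adjusted over the list alone. The lists passed camera with the preset correlation (adjusted p = 1.66e-04 for neuron, 2.20e-05 for synaptic transmission and 0.0171 for axon guidance), with adjusted p = 0.871 with an estimated correlation for each.

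The controls also differed from each other in these genes. The neuron list's median in control 2 was -0.66 log2 units from control 1, and the crispants lay 0.32 and 1.14 above controls 1 and 2. For synaptic transmission the controls differed by -0.36, with crispants 0.73 and 1.39 above controls 1 and 2. The neuronal members that rose numbered 24 without control 1, 9 without control 2, and 7 without crispant 1 and 7 without crispant 2. Synaptic members that rose numbered 19, 8, 1 and 0 in the same order, and axon guidance members 15, 9, 0 and 0.

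Genes of the neural crest and pharyngeal arches, from which the facial skeleton forms, had a median of -0.63. The transcription factor gene snai2 fell (-1.84 ± 0.30, 58.0 ± 11.9 to 16.1 ± 1.37 CPM), and the other 34 of 35 tested members did not pass, with 7 falls when adjusted over the list alone. Snai2 lost the threshold without crispant 1 (edgeR adjusted p = 0.117) or crispant 2 (0.0625). Camera gave adjusted p = 1.66e-04 with the preset correlation and adjusted p = 0.871 with an estimated correlation, where the unadjusted p was 0.0384, and fry gave adjusted p = 0.0168. Of 14 bone genes 2 fell, col10a1a (a collagen of bone and hypertrophic cartilage, -1.28 ± 0.23) and sparc (osteonectin, -0.86 ± 0.20), 0 rose and 12 did not pass, with 3 falls when adjusted over the list alone (camera adjusted p = 0.0194, and adjusted p = 0.871 with an estimated correlation). Of 24 cartilage genes sox5 rose (2.03 ± 0.47), the matrix gene ucmab fell (-1.62 ± 0.29) and 22 did not pass, with 2 rises and 4 falls when adjusted over the list alone. Among 52 genes of Wnt, Notch, Hedgehog, TGF-beta and BMP signalling only id1, a target of BMP signalling, passed in either direction (-1.19 ± 0.21), with 1 fall when adjusted over the list alone (camera adjusted p = 0.00684, and adjusted p = 0.871 with an estimated correlation). Each of col10a1a, sparc, sox5, ucmab and id1 lost the threshold without crispant 1 and without crispant 2 (edgeR adjusted p from 0.0637 to 0.356).

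In the list of non-collagen extracellular matrix 3 of 34 rose, 2 fell and 29 did not pass, with 5 rises and 6 falls when adjusted over the list alone. The rises included mmp13a (3.74 ± 0.41, edgeR adjusted p = 0.00721) and the metalloproteinase inhibitor timp2b (2.98 ± 0.32, 6.72 ± 1.12 to 53.2 ± 2.05 CPM), both past the threshold with each library left out. The falls were thbs1b, a thrombospondin (-1.66 ± 0.25), and postna, a periostin (-1.70 ± 0.33), and they lost the threshold without crispant 1 (edgeR adjusted p = 0.0986 and 0.0858), postna also without crispant 2 (0.0829). The neutrophil list shared its 3 rising genes, mmp13a, timp2b and mmp9, with the matrix list. Of its 13 tested members 10 did not pass, with 3 rises when adjusted over the list alone. Mmp9 was chosen after its values were seen. The myeloid peroxidase gene mpx, chosen after its values were seen, gave 0.19 ± 0.50. Control 2 exceeded control 1 by a neutrophil list median of 1.16. Of 28 proteoglycan core protein genes dcn, decorin, rose (1.53 ± 0.30) and 27 did not pass, with 1 rise when adjusted over the list alone. Of 36 genes of glycosaminoglycan synthesis and breakdown 0 passed by edgeR, also when adjusted over the list alone, with 5 at an unadjusted p below 0.05, 1 call by DESeq2 and 1 by limma-voom. The most abundant were gnsa (-0.73 ± 0.22) and hexb (-0.38 ± 0.26), while gnsb, given above as a rise, was not a member of this list. Of 21 collagen genes col4a2, a basement membrane chain, rose (2.28 ± 0.51) and 20 did not pass, with 1 rise and 1 fall when adjusted over the list alone. Dcn and col4a2 lost the threshold without crispant 1 and without crispant 2 (edgeR adjusted p from 0.161 to 0.277).

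Interferon response genes rose in 3 of 16 tested members, 0 fell and 13 did not pass, with 6 rises when adjusted over the list alone. Irf1b, an interferon regulatory factor, rose (1.87 ± 0.33, 10.7 ± 0.430 to 39.0 ± 7.38 CPM), as did the antiviral GTPase gene mxc (3.56 ± 0.67). The list passed camera with the preset correlation (adjusted p = 0.00994), with adjusted p = 0.871 with an estimated correlation, and 7, 7, 1 and 0 members rose without control 1, control 2, crispant 1 and crispant 2. Of 28 complement and acute phase genes c3a.2 (2.14 ± 0.38) and cp rose, cfhl4 fell (-2.02 ± 0.35) and 25 did not pass, with 4 rises and 1 fall when adjusted over the list alone. Of 38 immediate early and acute stress genes 5 rose, 0 fell and 33 did not pass, with 6 rises when adjusted over the list alone. Fosl1a, an AP-1 subunit, rose (2.46 ± 0.35, edgeR adjusted p = 0.0139) and passed with each library left out, and cebpb rose (57.8 ± 17.7 to 164 ± 2.62 CPM). Of 32 circadian clock genes 4 rose, 1 fell and 27 did not pass, with the same counts when adjusted over the list alone. The PAR bZIP genes hlfa (1.34 ± 0.20) and dbpa (3.35 ± 0.51) rose, and the nuclear receptor gene nr1d2b fell (-2.22 ± 0.47). Irf1b, cfhl4, cebpb and hlfa lost the threshold without crispant 1 and without crispant 2 (edgeR adjusted p from 0.0573 to 0.154), c3a.2 only without crispant 1 (0.110), and mxc, dbpa and nr1d2b only without crispant 2 (from 0.0528 to 0.0974).

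Markers of the cell types in which mammals express CSPG4 were mostly not past the threshold, as held for all genes, of which 672 of 12481 passed. Of 12 oligodendrocyte lineage genes plp1b, a myelin proteolipid gene, fell (152 ± 40.3 to 62.0 ± 2.57 CPM) and 11 did not pass, with 1 fall when adjusted over the list alone. Of 17 pericyte and mural cell genes en1b rose (2.08 ± 0.44), foxc1b fell (-1.19 ± 0.28) and 15 did not pass, with 1 rise and 5 falls when adjusted over the list alone. En1b and foxc1b encode transcription factors that other tissues of the head also use. Plp1b, en1b and foxc1b lost the threshold without crispant 1 and without crispant 2 (edgeR adjusted p from 0.0625 to 0.388). Of 11 endothelial, 18 radial glia and astroglia, 30 cell cycle and 24 microglia and macrophage genes, 0 passed by edgeR, also when adjusted over the list alone. Unadjusted p-values below 0.05 were found for 0, 3, 2 and 2 of them in that order, and DESeq2 and limma-voom each called 1 microglia and macrophage gene and 0 of the others. Their most abundant members were sox7 (-0.34 ± 0.28) and fli1a (-1.04 ± 0.48) for endothelium, glula (-0.22 ± 0.19) and slc1a2b (0.39 ± 0.29) for glia, ccnd1 (0.06 ± 0.22) and mcm4 (-0.31 ± 0.21) for the cell cycle, and apoeb (-0.60 ± 0.17) and apoc1 (-0.60 ± 0.23) for microglia and macrophages.

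The authors' deposited table listed 527 genes with a highest adjusted p of 0.04998, and it was set beside the counts to see whether both give 1 direction. Whether it holds the same comparison as the counts is not settled by its title, which also carries a variant-like name. In the authors' deposited table the fold change equalled the control score divided by the crispant score in all 527 genes, within a relative tolerance of 0.0001. Both scores lay below 0 for 201 genes of the authors' deposited table and above 0 for 326, and the log2 fold change pointed the same way as crispant minus control score in 201. Of the 409 genes of the authors' deposited table tested here, 22 passed edgeR's threshold, where independent lists would share 22.0, and 12 of the 22 went the same way as the difference of the deposited scores. The sign of the difference of scores in the authors' deposited table matched the counts in 49.6% of genes (95% exact binomial interval 44.7 to 54.6%), with r = 0.08 across genes. The log2 fold change of the authors' deposited table, taken as it stands, control over crispant, had the sign of the crispant over control counts in 56.2% (51.3 to 61.1%), with Pearson r = 0.24 and Spearman rho = 0.16 across genes, which are not independent. Turned to crispant over control, the log2 fold change of the authors' deposited table had that sign in 43.8% (38.9 to 48.7%), with r = -0.24 and rho = -0.16. The fibrinogen gene fgg, chosen after its values were seen, had the largest deposited log2 fold change (8.95) of the 409 genes tested here. For fgg the authors' deposited table gave scores of -0.01 for crispants and -3.00 for controls and a fold change of 495. Its counts were 359 and 476 in controls and 404 and 205 in crispants (-0.64 ± 0.33, edgeR adjusted p = 0.287).

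**Figure D3:**
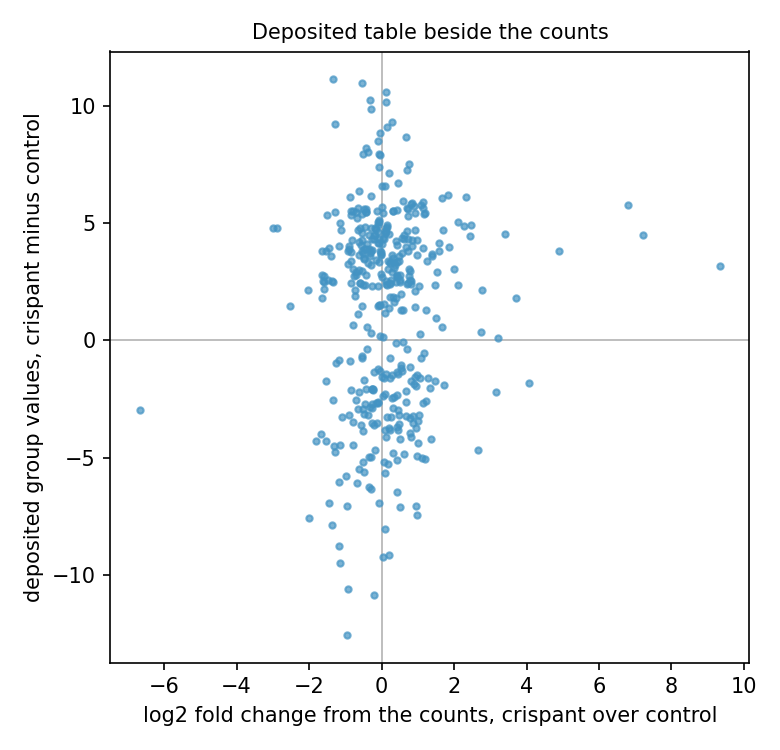
Log2 fold change from the counts, crispant over control, on the horizontal axis, and crispant minus control score of the authors' deposited table on the vertical axis, for 409 genes found in both, each point a gene. The same sign was found in 49.6% of the genes.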

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

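Of 1429 alternative values for 110 named genes, 1251 stayed on the same side of the threshold, 152 kept the direction but no longer passed, 25 newly passed and 1 reversed. A change of sign counted as reversed only where a value passed. Values that passed in neither fit could change sign among the 1251, as ccnd1 did (0.06 with all libraries, -0.09 at its lowest with a library left out). The reversed value was that of rbp4l, 0.02 with all libraries, -0.36 without control 2 and 0.55 without control 1, the last 2 past the threshold. Of 90 named genes past the threshold, 20 stayed past it with each library left out, 10 lost it without crispant 1 only, 11 without crispant 2 only, 49 without either, and 0 without a control. Among 169 alternative list tests, 139 were the same and 30 weaker. The weaker ones came with the estimated correlation, with fry, or with control 1, control 2 or crispant 1 left out. With each library left out the count of changed genes ran from 192 to 4128, that of rises from 100 to 2350 and that of falls from 74 to 1778, against 672, 354 and 318. The lone library of a group is then assumed to vary like the other group, so leaving out a control rests on the closer crispants. Without a filter on low counts 1806 genes passed of 19114 tested, with 1019 rises and 787 falls. DESeq2 called 1218, with 715 and 503, and an FDR of 0.1 gave 1606, with 892 and 714. Library size alone gave 625 rises. The replicate block gave 1356 genes, 764 higher and 592 lower. The labels do not say what the numbers share. Deviations of same-numbered libraries correlated at -0.007 across genes, which with 1 difference per group cannot show whether they shared a batch. For these counts the cause was not tested. No gene called with all libraries was called in the opposite direction in another fit (0 crossed). With an estimated correlation 0 of 13 lists passed (1 at an unadjusted p below 0.05) and with fry 1 of the 13 did (9 of the 13 at an unadjusted p below 0.05). The depth allows no statement on genes under about 0.5 CPM, cspg4 among them.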

Other observations

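For the gene groups not described so far, the counts of calls are to be read beside the 672 of 12481 genes that passed over all genes. Of 79 skeletal muscle genes 3 rose, 3 fell and 73 did not pass by edgeR, with 4 rises and 3 falls when adjusted over the list alone. The calcium release channel gene ryr1b rose 14.5-fold, from 1.58 ± 1.47 to 23.3 ± 2.23 CPM (SD, n = 2), and jph1a, which joins the same channel to the surface membrane, rose as given above, while the troponin gene tnni2b.1 (-1.05 ± 0.20 SE) and the adenylate kinase gene ak1 (-1.11 ± 0.21) fell. Of 15 cardiac genes 0 passed, also when adjusted over the list alone (3 at an unadjusted p below 0.05, 0 by DESeq2 and 1 by limma-voom), and myl4 gave -0.12 ± 0.23 and cmlc1 -0.33 ± 0.29. Among 22 erythrocyte genes the embryonic globin gene hbae1.3 rose (1.52 ± 0.22), rhag fell (-1.17 ± 0.27) and 20 did not pass, with 1 rise and 1 fall when adjusted over the list alone. A second entry under the name hbae1.3 gave a log2 fold change of 0.96, so the value of the single copy is uncertain. The peptide transporter gene slc15a1b rose 6.34-fold, from 18.5 ± 12.6 to 117 ± 4.73 CPM, as the only call among 31 genes of exocrine pancreas and intestine, with 2 rises when adjusted over the list alone. The median of that list was -0.93, control 2 exceeded control 1 by a list median of 1.54, and the crispants lay 0.58 and -1.3 from controls 1 and 2. Its falling members numbered 22 without control 1 and 0 without control 2. Of 48 genes of fatty acid and lipid metabolism 4 fell, among them the desaturase gene fads2 (-2.31 ± 0.39) and apoa2 (-1.11 ± 0.22), 0 rose and 44 did not pass, with 5 rises and 8 falls when adjusted over the list alone. Of 22 genes of cholesterol synthesis 0 passed, also when adjusted over the list alone (6 at an unadjusted p below 0.05, 0 by DESeq2 and 1 by limma-voom), with abca1a at -0.51 ± 0.24 and npc1 at -0.48 ± 0.23. Of 50 genes of amino acid, purine and one-carbon metabolism 1 rose, 4 fell and 45 did not pass, with 2 rises and 6 falls when adjusted over the list alone. The polyamine enzyme gene odc1 rose (1.61 ± 0.22), and pah (-1.23 ± 0.23) and hpda (-1.77 ± 0.36), which break down phenylalanine and tyrosine, fell (camera adjusted p = 0.0243 for the list, and adjusted p = 0.871 with an estimated correlation). Of 32 glycolysis genes pfkpa (1.51 ± 0.25) and the neuronal enolase gene eno2 (1.54 ± 0.35) rose, the muscle enolase gene eno3 fell (-1.14 ± 0.26) and 29 did not pass, with 2 rises and 2 falls when adjusted over the list alone.

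Among 31 hormone genes thyroglobulin, tg (-1.38 ± 0.23), and growth hormone, gh1 (-2.12 ± 0.46), fell, the deiodinase gene dio3b rose (1.48 ± 0.33) and 28 did not pass by edgeR, with 2 rises and 2 falls when adjusted over the list alone. Of 39 genes of MAPK and growth factor signalling raf1b rose (1.24 ± 0.21), the FGF antagonist gene spry2 (-1.58 ± 0.34) and the receptor gene fgfr4 (44.5 ± 4.81 to 18.1 ± 0.412 CPM) fell and 36 did not pass, with 2 rises and 2 falls when adjusted over the list alone. In the brain patterning list foxg1a (1.42 ± 0.26) and en1b rose, and 37 of 39 did not pass, with 2 rises when adjusted over the list alone. Of 40 genes of the heat shock and unfolded protein response 3 rose, among them the calreticulin genes calr3a (42.9 ± 3.40 to 106 ± 2.29 CPM) and calr (1.29 ± 0.27), the collagen chaperone gene serpinh1b fell (-1.90 ± 0.38) and 36 did not pass, with 4 rises and 1 fall when adjusted over the list alone. Of 26 p53 response genes tp53inp1 rose (1.41 ± 0.22) and 25 did not pass, with 3 rises and 2 falls when adjusted over the list alone. The autophagy kinase gene ulk1b rose (5.18 ± 1.18), from 2 and 0 counts to 43 and 47, sqstm1 fell (-1.42 ± 0.26) and 41 of 43 lysosome and autophagy genes did not pass, with 1 rise and 1 fall when adjusted over the list alone. Of 38 phototransduction genes gngt2a, a cone transducin gene, fell (-2.97 ± 0.48) and 37 did not pass, with 1 fall when adjusted over the list alone. The phototransduction median in control 2 was -0.99 log2 units from control 1, and the crispants lay -0.29 and 0.75 from controls 1 and 2. Of 24 inner ear genes s100t (-1.43 ± 0.28) and sparc fell and 22 did not pass, with 1 rise and 4 falls when adjusted over the list alone, and of 25 pigment cell genes paics fell (-1.25 ± 0.27) and 24 did not pass, with 1 fall when adjusted over the list alone. Of 19 genes of the retinal pigment epithelium, 23 of the inner retina and 6 trunk Hox genes 0 passed, also when adjusted over the list alone. At an unadjusted p below 0.05 there were 1, 2 and 1 in that order, DESeq2 called 1, 1 and 0, and limma-voom called 0, 1 and 0. Their most abundant members were rbp4l at 0.02 ± 0.27, rbp3 at -0.59 ± 0.29, gng13b at 0.53 ± 0.33, pax6a at 1.47 ± 0.35, cdx1a at -2.04 ± 0.75 and hoxb8a at 0.82 ± 0.85. Of the genes named in these paragraphs ryr1b, slc15a1b and gngt2a passed with each library left out, and the other calls were lost without crispant 1, crispant 2 or both. The signs of median, mean and camera test differed in 9 lists, cartilage, non-collagen matrix, skeletal muscle, cardiac muscle, microglia, heat shock, circadian clock, fatty acid metabolism and lysosome.

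The tests below of skin share, mitochondrial share, short transcripts, depth, independent loss in the controls and the deposited fold changes were chosen after the results were seen, and those of mitochondrial share, depth and the ratio of scores replaced earlier tests that could not decide. Of the tested epidermal, lens, ribosomal protein and liver genes 14, 21, 35 and 8 fell, with adjusted p = 0.871 for each list with an estimated correlation. Mitochondrial genes and CR383676.2 took a larger share of crispant counts. The share left to other genes moved by -0.28 log2 units in the pair of libraries with the largest drop. With library size as the only scaling, the 4 list medians over all tested members were -0.58, -1.21, -0.70 and -0.66. Their 95% bootstrap intervals ended at -0.37 or lower, but take members as independent and hold no spread between libraries. With TMM, crispants lay -1.44 and -1.33 from controls 1 and 2 for lens genes, and -0.78 and -0.86 for ribosomal protein genes. For these lists the larger share is argued against as the whole cause. For epidermal and liver genes it stays open. There the crispants lay -0.45 and -0.46 from control 1, and the controls differed by 0.38 and 0.63. A smaller share of skin stays open. The SD of log2 fold changes over 29 epidermal genes of at least 50 CPM was 3.92 times their median standard error (0.94 against 0.24), so they did not fall by 1 common amount. The test had no reference list, and members that other epithelia also use would not fall alike, so it decides nothing on the share of skin. Loss of short transcripts stays open for the ribosomal protein genes, since transcript lengths were not analysed here and the median of the oxidative phosphorylation genes, 0.56 log2 units higher (95% bootstrap interval 0.30 to 0.92) at -0.24, decides nothing without them. A response to the targeting of cspg4, and a difference in age or dissection between the groups, remain possible and untested, and near-identical copies could move single crystallin and ribosomal genes. Only the crispants are labelled as given Cas9 and a guide RNA, so other effects of that treatment cannot be told apart from the targeting of cspg4.

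A group of 44 genes had 0 counts in both controls and at least 20 in both crispants (1 gene in reverse, 0 in mixed pairs of libraries). Scaled by the totals, at least 18.8 counts of each would be left in a control. That bound was fixed in advance by the cut-off of 20 counts and the near-equal totals. The near-equal totals themselves argue against greater depth of the crispants as the cause. A gene was counted in each library where it had 20 to 200 counts, so it could count in both libraries of a group. Of these cases, 1.5% between the controls (205 of 13668, 95% exact interval 1.3 to 1.72%) and 0.184% between the crispants (27 of 14645, 0.122 to 0.268%) had 0 in the other library of the group. Such zeros were more frequent between the controls, though the intervals take repeated genes as independent and are too narrow. Random loss of molecules in the controls stays open. The share of 1.5% met the prediction set beforehand but sets a single 0 against the joint 0 of 0.707% of genes (44 of 6225), and so decides nothing. Of these 6225 genes 98 had 0 in control 1 and 213 in control 2, and if genes of like crispant count are lost alike, loss that struck the controls independently predicts 8.82 joint cases, below the interval of 32.0 to 59.07 around the 44. A loss shared by both controls could account for the rest and cannot be separated here from a rise in the crispants, so genes such as gnsb and gria3a are candidates for a repeat in other libraries.

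The fold changes of the authors' deposited table often differed in direction from the counts. The fold change in the authors' deposited table equals a ratio of log-scale scores in 527 of 527 genes, and such a ratio points opposite ways for scores below and above 0. This is argued against as the whole cause, since the difference of scores in the authors' deposited table, which undoes the ratio, had the sign of the counts in 49.6% of genes (95% exact interval 44.7 to 54.6%). The 4 columns of counts alone cannot have given all scores of the authors' deposited table, since 16 of its genes had 0 counts in all 4 libraries. Among these, mrpl51 had scores of -2.08 for crispants and -0.04 for controls, and micos13 had -2.64 and -0.08. Both were chosen after their values were seen. Which animals, libraries or counts gave the scores is not known. Whether this accounts for the directions of the other genes is a candidate explanation and stays open.

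With 2 libraries per group there are 3 splits of the 4 libraries into 2 and 2, too few for a share under 0.05. The real split gave 672 genes, 1 of 3 splits gave as many, and the highest of the others was 0.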
